A study of Homo sapiens with 72 samples.

How the data were processed

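Transcript levels were measured in 3 clones of CEM, a human T-lineage acute lymphoblastic leukemia line, on Affymetrix HG_U95Av2 arrays. Each clone was sampled 2, 8, 12 and 20 h after dexamethasone, a synthetic glucocorticoid, or its ethanol vehicle was added, which gave 24 groups of 3 arrays and 72 arrays in all. Per the labels' protocols, the 3 arrays of a group came from separate cultures seeded from log-phase cells, total RNA was isolated with a Qiagen kit, and biotin-labelled target was made by in vitro transcription with an ENZO kit. The labels give a single micromolar concentration of dexamethasone, written in a notation that leaves its exact value open. Groups and the replicate letters A, B and C were taken from the sample titles.

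The deposited values are intensities on a linear scale, 1 column per array, for 12624 probe sets. The software that turned the scans into these intensities is not given in the sources used here, and probe-level files and detection calls were not used here. In each of the 72 columns the mean after trimming 2% at both ends lay between 498.4 and 499.8, so the authors' intensities had already been scaled to 1 common trimmed mean per array. All columns matched a sample, with 0 columns left over. Between any 2 arrays at most 0.38% of the probe sets held identical values, and the correlation of log2 values between 2 replicates of a group ran from 0.843 to 0.9841 with a median of 0.966, so no array was treated as a repeat of another.

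Control probe sets (66) were left out. Exact zeros occurred in 25 probe sets on the 6 arrays of replicate A at 20 h and on none of the other arrays. Those 25 probe sets were left out, a choice made after the values were seen. The 6 arrays were treated as a possible technical set. Probe sets were named through the platform's annotation table, whose symbols were looked up by Entrez identifier in a RefSeq table (10934 probe sets, of which 0 changed symbol). Of 12558 probe sets, 10943 had 1 symbol, 545 had several and 1070 had none or were not listed. Only probe sets with 1 symbol were used, and for each of 8211 genes the brightest over all 72 arrays stood for the gene.

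Values below the 25th percentile of all values, 34.1, were raised to it and log2 was taken, so fold changes of dim genes are understated. Arrays were not scaled further, since their log2 75th percentiles lay between 8.92 and 9.2. Genes above the median of all values (139.5) on at least 3 arrays were tested, which left 5883. Array medians ran from 109.1 to 218.3 and 25th percentiles from 23 to 73.6, so the low end of the signal differed between arrays of 1 common trimmed mean. The number of arrays limits the precision of each value.

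Differences were tested with limma 3.58.1 in R 4.3.3. One linear model with 24 group means was fitted to all 72 arrays, with moderated variances that follow the mean level and 48 residual degrees of freedom. A gene was counted as past the threshold at a Benjamini-Hochberg adjusted p below 0.05 over the 5883 genes of a contrast. There were 12 contrasts of dexamethasone against ethanol (clone by time). Another 8 were differences of such responses between clones, and 3 compared the ethanol cultures of the clones averaged over the 4 times. Errors after ± are standard errors of the log2 fold change from this model. All adjusted p-values of genes are limma's.

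For groups of genes, 39 lists were written before the data were examined. Of these, 37 had at least 5 tested members and were tested with limma's camera at its preset correlation between genes, adjusted over the lists of a contrast. Each call was repeated with an estimated correlation and with fry. Members of a list were also counted as past the threshold when adjusted over the list alone. The lists of anti-apoptotic BCL2 family genes and of myeloid markers had 4 tested members each and were not tested as lists. Genes were named by a rule of the same date. At 20 h in CEM C7-14 and in CEM C1-6 it took the 12 highest and 12 lowest past the threshold whose 3 dexamethasone arrays all lay on 1 side of the 3 ethanol arrays, and in the other dexamethasone contrasts 5 and 5. It took 8 and 8 for sensitive against resistant, 5 and 5 for CEM C7-14 against CEM C1-6, 10 and 10 for each ethanol comparison, up to 3 and 3 members of each called list, and a panel of 24 genes. BTG2, PER1 and SGK1 of the panel were not tested.

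Calls shared by clones in the same direction were set beside the number for independent lists of equal length. The clones share no arrays, but a shared spread per gene can raise the overlap. Replicate letters were checked by correlating, across genes, the deviations of the dexamethasone and ethanol arrays of 1 letter from their group means. At 20 h in CEM C7-14 these correlations were 0.59, 0.36 and 0.40 for letters A, B and C, and in CEM C1-6 they were 0.28, 0.39 and 0.57. In each of the other 10 clone and time combinations at least 1 letter was at or below 0.1, and there the letters were not taken to pair the cultures.

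The model was tested on simulated data made from the real arrays' deviations moved between groups, with 200 of 5883 genes changed, in 20 simulations. Genes changed by 1 log2 unit were recovered in 57% of cases in CEM C7-14 at 20 h, 60% in CEM C1-6 at 20 h and 54.1% in CEM C7-14 at 12 h. Of the simulated calls, 0.944% were wrong in CEM C7-14 at 8 h and 3.2% at 12 h, against 37.7% at 20 h. In CEM C1-6 the wrong share was 3.6% at 8 h, 12% at 12 h and 55.1% at 20 h. For sensitive against resistant at 20 h it was 66.2%. These shares pool the calls of all 20 simulations, with arrays moved singly. With no gene changed the median count at 20 h was then 0.5 in CEM C7-14, 0 in CEM C1-6 and 25 for sensitive against resistant. It was 0 in each with letters kept together, so single simulations with many wrong calls can carry a pooled share. The spread of the 20 h arrays was therefore larger than the spread that all groups share in this model. With dexamethasone and ethanol arrays of 1 letter kept together and no gene changed, the highest of 20 simulated counts was 299 in CEM C7-14 at 20 h and 75 in CEM C1-6 at 20 h, and with the 18 arrays of 20 h alone it was 0 in both. With arrays moved singly it was 1412 and 1297, and with the 18 arrays alone 187 and 284, above the 62 and 116 genes of the real data. Counts at 20 h are given with those from the 18 arrays of that time, and both carry this doubt. The changed list was called in 18 to 20 of 20 simulations. Of 720 random lists 0 were called, which is no guide to correlated genes.

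The alternatives were other floors (10th and 40th percentile), no filter and a stricter filter, quantile normalization, centring on the array median, no variance trend, the arrays of the compared groups alone, all probe sets, a replicate block, and leaving out each array in turn. Further alternatives were chosen after the data were seen. They were the arrays of 1 time alone (with and without the replicate block), array quality weights, the array's 25th percentile or its GAPDH 3' to 5' ratio as a covariate, the 6 arrays of replicate A at 20 h as a block, and the same arrays left out. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.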

Results

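The series followed gene expression in 3 clones of the CEM human T-cell leukemia line through the first 20 h of treatment with dexamethasone, a synthetic glucocorticoid that kills sensitive lymphoid leukemia cells. CEM C7-14 is a subclone of a sensitive clone. CEM C1-6 and CEM C1-15 both descend from a resistant clone, and CEM C1-6 had spontaneously regained sensitivity while CEM C1-15 remained resistant. Each clone had 3 dexamethasone and 3 ethanol cultures at 2, 8, 12 and 20 h, with 1 array per culture. The design asks which transcripts respond in the sensitive clones, in which order, and which of those responses are missing in the resistant clone. All 72 arrays carried the same scaled mean intensity, and their medians ran from 109.1 to 218.3. Differences are given as log2 fold change ± SE from limma with n = 3 arrays per group, and 5883 genes were tested in each comparison.

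In CEM C7-14 at 2 h 4 genes rose and 0 fell, and 3 of them belong to the list of glucocorticoid-inducible genes (252 at an unadjusted p under 0.05, against 294 by chance). The 4 were the antiproliferative gene BTG1 (1.83 ± 0.25, adjusted p = 8.58e-06), the cytokine signalling inhibitor SOCS1 (1.80 ± 0.35), FKBP5, a co-chaperone of steroid receptors (1.31 ± 0.28), and, outside the list, the centrosomal gene CEP164 (1.28 ± 0.27). At 8 h 18 genes rose and 3 fell. SOCS1 had reached 3.14 ± 0.35, BTG1 2.37 ± 0.25, the exoribonuclease gene ISG20 2.03 ± 0.29 and FKBP5 1.95 ± 0.28. The receptor's own gene NR3C1 rose by 1.54 ± 0.18 and NFKBIA, an inhibitor of NF-kB, by 0.83 ± 0.18. The folate enzyme gene MTHFD2 fell by 0.56 ± 0.13 and BTG3 fell by 0.67 ± 0.16. Both of these calls were lost without any 1 of the 6 arrays (adjusted p = 0.0564 to 0.242 and 0.057 to 0.322) and with arrays centred on their medians. At 12 h 41 genes rose and 19 fell. Those that rose included TXNIP, which binds thioredoxin (1.54 ± 0.25), the integrin gene ITGA6 (1.22 ± 0.19) and the interleukin 7 receptor gene IL7R (0.98 ± 0.26). The growth regulator MYC fell by 1.33 ± 0.22 (adjusted p = 5.15e-05), the Notch target HES1 fell by 1.74 ± 0.35, and RAG1, which cuts DNA for antigen receptor rearrangement, fell by 1.31 ± 0.31. NFKBIA was lost without ethanol B or dexamethasone C (adjusted p = 0.182 and 0.205), and RAG1 without ethanol B, ethanol C or dexamethasone A (adjusted p = 0.0685, 0.067 and 0.3). IL7R passed with dexamethasone C left out and not with any other (adjusted p = 0.0607 to 0.425).

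Of 29 tested genes in the list of glucocorticoid-inducible genes, 3, 8 and 13 rose at 2, 8 and 12 h and 0 fell (6, 8 and 16 when adjusted over the list alone). The list's camera call held with an estimated correlation at each of these times (adjusted p = 0.00054, 2.26e-08 and 5.62e-11). In the list of MYC and MYC-activated genes 2 of 29 fell at 12 h (5 adjusted over the list alone, adjusted p = 0.0049 with an estimated correlation). Of 23 ribosome biogenesis genes 0 passed over all genes at 12 h and 6 fell when adjusted over the list alone (adjusted p = 0.00735 with an estimated correlation). Autophagy and lysosome genes shifted up at 12 h (0 of 20 past over all genes, 2 over the list alone, adjusted p = 0.0322 with an estimated correlation). This call was lost with the floor at the 40th percentile, the stricter filter, median centring or array weights (adjusted p = 0.0601, 0.0514, 0.0592 and 0.0565). It was also lost without ethanol C, dexamethasone A or dexamethasone C (adjusted p = 0.0895, 0.0534 and 0.106). For TSC22D3 at 8 h the brightest probe set gave -0.16 ± 0.26, while another probe set of this gene passed the threshold upward. The count at 2 h was 1 without ethanol B or without ethanol C and 2 without dexamethasone B or without dexamethasone C. BTG1 passed without any single array, while FKBP5 (adjusted p = 0.339, 0.283, 0.305 and 0.147) and CEP164 (adjusted p = 0.675, 0.262, 0.365 and 0.134) were lost without each of these 4, and SOCS1 was lost without ethanol B, ethanol C or dexamethasone C (adjusted p = 0.339, 0.0692 and 0.134). With quantile normalization BTG1 alone passed (adjusted p = 0.0539 for FKBP5 and SOCS1 and 0.145 for CEP164), and centring on array medians ended the calls of FKBP5 and CEP164 (adjusted p = 0.0822 and 0.206). The count at 8 h was 12 without ethanol B, and at 12 h it was 39 without dexamethasone B and 33 (29 rose, 4 fell) when arrays were centred on their medians.

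At 20 h 310 genes passed in CEM C7-14 (62 with the 18 arrays of 20 h alone), of which 157 rose and 153 fell. SOCS1 rose by 4.01 ± 0.35 (16.1-fold, adjusted p = 1.35e-13), from a mean intensity of 56.4 ± 17 (SD) to 882.5 ± 114. TUBA4A, an alpha-tubulin gene, rose by 3.52 ± 0.30, ISG20 by 3.30 ± 0.29 and BTG1 by 3.26 ± 0.25 (9.57-fold). PIK3IP1, an inhibitor of PI3-kinase, rose by 2.86 ± 0.38, NFIL3, a bZIP transcriptional repressor, by 2.58 ± 0.19, and RCAN1, an inhibitor of calcineurin, by 2.34 ± 0.21 (adjusted p = 1.13e-12). MYC fell by 1.76 ± 0.22 (adjusted p = 2.38e-08), from an intensity of 2811 ± 610 (SD) to 837.5 ± 253, and 3 other MYC probe sets had the same sign. HES1 fell by 2.90 ± 0.35 and RAG1 fell by 1.91 ± 0.31.

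Lists of growth-related genes shifted down at 20 h in CEM C7-14. In the list of MYC and MYC-activated genes 16 of 29 fell and 0 rose (21 fell when adjusted over the list alone; median -0.62, adjusted p = 1.99e-05 with an estimated correlation). Among ribosome biogenesis genes 13 of 23 fell (17 adjusted over the list alone, adjusted p = 0.000139 with an estimated correlation). They included RRP12 (-1.87 ± 0.41) and BYSL (-1.15 ± 0.16), which act in assembly of the small subunit, and NOLC1, a nucleolar phosphoprotein (-1.09 ± 0.22). Of 16 heat shock protein genes 6 fell (8 adjusted over the list alone, adjusted p = 0.00757 with an estimated correlation), among them FKBP4 (-0.95 ± 0.21) and STIP1 (-0.86 ± 0.20), which work with the HSP90 machinery. Of 22 amino acid response and tRNA synthetase genes 5 fell (10 adjusted over the list alone, adjusted p = 0.0151 with an estimated correlation), led by MTHFD2 (-1.07 ± 0.13), with NARS1 (-0.68 ± 0.16) and IARS1 (-0.66 ± 0.16), which charge tRNA. ODC1, the first enzyme of polyamine synthesis, fell by 1.01 ± 0.19. FKBP4 was lost without ethanol A (adjusted p = 0.077), STIP1 without dexamethasone C (adjusted p = 0.0922) and NARS1 without ethanol A or dexamethasone B (adjusted p = 0.0609 and 0.0564).

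Of 9 cell cycle inhibitor genes 3 rose, over all genes and adjusted over the list alone (adjusted p = 0.0168 with an estimated correlation), among them CDKN1B, which encodes p27 (0.71 ± 0.21), and TOB1 (0.68 ± 0.16). CDKN1B passed with ethanol A left out and was lost without any other single array (adjusted p = 0.0532 to 0.244). It was also lost with quantile normalization or median centring (adjusted p = 0.134 and 0.321) and with the 18 arrays of 20 h alone (adjusted p = 0.517). TOB1 was lost without ethanol B (adjusted p = 0.0774). ER chaperone genes shifted down (0 of 12 past in either adjustment, adjusted p = 0.0218 with an estimated correlation). The cholesterol synthesis genes DHCR7 (-0.81 ± 0.21), MSMO1 (-0.70 ± 0.21) and LSS (-0.63 ± 0.16) fell, but the call of their list of 17 (4 fell when adjusted over the list alone) was lost (adjusted p = 0.0565 with an estimated correlation). The thymocyte list had 5 of 25 lower and 2 higher (6 and 3 adjusted over the list alone), and its call was lost as well (adjusted p = 0.0887 with an estimated correlation). Its members included RAG1 and CD1E (-1.40 ± 0.43), which fell, and LEF1 (0.64 ± 0.14) and TAL1 (0.66 ± 0.21), which rose. TAL1 was lost without any 1 of the 6 arrays (adjusted p = 0.0649 to 0.192) and under 8 of 16 other alternatives. CD1E passed with dexamethasone B left out and was lost without any other (adjusted p = 0.0533 to 0.256). Among glucocorticoid-inducible genes 15 of 29 rose (16 adjusted over the list alone, adjusted p = 2.78e-10 with an estimated correlation), with FKBP5 at 2.75 ± 0.28, CD69 at 2.27 ± 0.27 and TSC22D3, a leucine zipper gene induced by the hormone in lymphocytes, at 0.92 ± 0.26. NR3C1 rose by 1.72 ± 0.18 (3.29-fold), with 2 other probe sets also past the threshold upward. Without ethanol A, ethanol B or dexamethasone C the calls of DHCR7 (adjusted p = 0.0952, 0.12 and 0.196) and MSMO1 (adjusted p = 0.25, 0.124 and 0.555) were lost. LSS was lost without ethanol B or dexamethasone A (adjusted p = 0.0529 and 0.0731). TSC22D3 was lost without ethanol A, dexamethasone B or dexamethasone C (adjusted p = 0.291, 0.156 and 0.0865).

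Of 10 pro-apoptotic BCL2 family genes 1 rose at 20 h in CEM C7-14, in either adjustment. BCL2L11, which encodes BIM, was at 0.47 ± 0.33 (adjusted p = 0.58). None of the 4 tested anti-apoptotic genes passed in limma, with BCL2 at 0.21 ± 0.34, MCL1 at 0.33 ± 0.15 and BCL2L1 at -0.35 ± 0.31. The arrays of 20 h had a larger spread than the one shared by all groups. Without dexamethasone B 195 genes passed at 20 h in CEM C7-14. Centring on array medians gave 165 (83 rose, 82 fell).

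**Figure D1:**
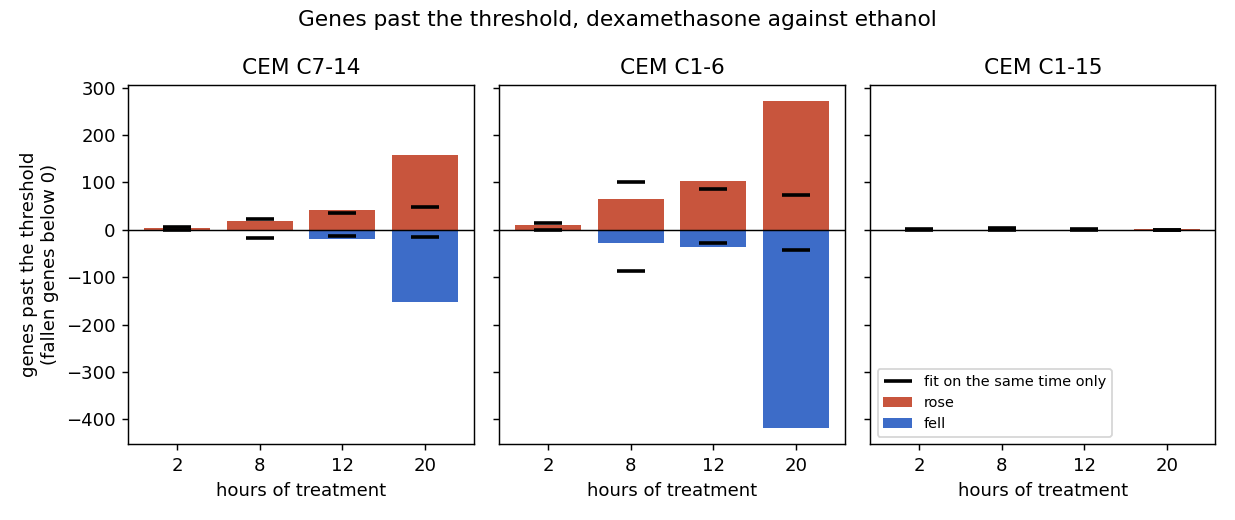
Numbers of genes past the threshold (adjusted p below 0.05 in limma, of 5883 tested) for dexamethasone against ethanol, by clone and hours of treatment; bars above 0 count genes that rose, bars below 0 genes that fell, and black lines give the counts from the 18 arrays of each time alone. CEM C7-14 went from 4 genes at 2 h to 310 at 20 h (62 from the arrays of 20 h alone), CEM C1-6 from 11 to 689 (116), and CEM C1-15 had 0, 0, 0 and 2.

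CEM C1-6, the clone that had regained sensitivity, responded with many of the same hormone-induced genes. At 2 h 11 genes rose and 0 fell. The largest rise was in CRYBG1, a gene of the crystallin beta-gamma family (2.08 ± 0.27, adjusted p = 9.97e-07), followed by SOCS1 (1.83 ± 0.35), DDIT4, an inhibitor of mTORC1 (1.73 ± 0.30), BTG1 (1.44 ± 0.25) and ZFP36L2, which destabilises mRNA (1.41 ± 0.26). At 8 h 64 genes rose and 29 fell, with SOCS1 at 3.46 ± 0.35, FKBP5 at 2.53 ± 0.28, the inositol phosphatase gene INPP1 at 2.46 ± 0.37, ISG20 at 2.40 ± 0.29 and NR3C1 at 1.18 ± 0.18. ZBTB16, which encodes the zinc finger repressor PLZF, rose by 1.98 ± 0.49. ETV5, an ETS transcription factor, fell by 1.40 ± 0.33, the corepressor gene TLE3 fell by 1.44 ± 0.41 and the D-type cyclin gene CCND3 fell by 0.77 ± 0.17. At 12 h 102 genes rose and 37 fell. HES1 fell by 1.84 ± 0.35, MYC fell by 1.31 ± 0.22 (adjusted p = 3.93e-05), LIG4, a DNA ligase gene, fell by 1.52 ± 0.36, and the integrin gene ITGAL fell by 1.09 ± 0.23, while the integrin gene ITGA6 rose by 1.63 ± 0.19 and GLRX, a glutaredoxin gene, by 1.41 ± 0.22. TLE3 was lost without any single array besides dexamethasone C (adjusted p = 0.055 to 0.374) and under 7 of 14 other alternatives. ETV5 at 8 h was lost without ethanol B, ethanol C or dexamethasone B (adjusted p = 0.0907, 0.059 and 0.101). ZBTB16 at 8 h was lost without ethanol C, dexamethasone A or dexamethasone B (adjusted p = 0.211, 0.0646 and 0.105), and LIG4 without ethanol C or dexamethasone A (adjusted p = 0.0811 and 0.298). ITGAL was lost without ethanol A (adjusted p = 0.0541).

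Of the 29 glucocorticoid-inducible genes 7, 14 and 16 rose at 2, 8 and 12 h in CEM C1-6 (10, 16 and 17 adjusted over the list alone, with 0, 1 and 1 lower). The list was called with an estimated correlation at each time (adjusted p = 1.15e-09, 1.03e-11 and 3.89e-11). Metallothionein genes, which bind zinc and copper, rose in CEM C1-6: 1, 4 and 6 of 8 at 8, 12 and 20 h (4, 5 and 6 adjusted over the list alone, adjusted p = 0.0323, 0.0284 and 0.0117 with an estimated correlation). MT1X was at 1.25 ± 0.29 at 12 h (lost without ethanol A or dexamethasone A, adjusted p = 0.106 and 0.0972), and MT1H reached 1.09 ± 0.18 at 20 h. MT1E, the gene that passed at 8 h, was lost without any 1 of the 6 arrays at 8 h (adjusted p = 0.0845 to 0.237) and at 12 h (adjusted p = 0.0646 to 0.211). At 12 h MT1H was lost without 4 of them (adjusted p = 0.0854 to 0.242), so that without ethanol A all 3 of these genes were lost. At 12 h the calls of MYC and MYC-activated genes (1 fell, 3 adjusted over the list alone) and of ribosome biogenesis genes (1 fell, 3 over the list alone) were lost (adjusted p = 0.31 and 0.215 with an estimated correlation). The 12 h dexamethasone arrays had a lower 25th percentile than the ethanol arrays (27.5 ± 3.7 against 36.5 ± 7.98, SD), and centring on array medians turned the 12 h split into 148 that rose and 7 that fell, with the median of all genes moved to 0.19. The 8 h count was 59 without ethanol A, 53 without dexamethasone B and 53 (33 rose, 20 fell) with arrays centred on their medians. The 2 h count was 6 with that centring, and the 12 h count was 76 without dexamethasone A.

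At 20 h 271 genes rose and 418 fell in CEM C1-6. The myoglobin gene MB rose by 4.43 ± 0.51 (21.6-fold), from an intensity of 39.5 ± 24.5 (SD) to 947.5 ± 247, and INPP1 rose by 4.36 ± 0.37 (20.5-fold). SOCS1 rose by 4.16 ± 0.35 (17.9-fold, adjusted p = 4.97e-14), CRYBG1 by 3.87 ± 0.27 and SMOX, a spermine oxidase gene, by 3.45 ± 0.41. The growth factor gene TGFB3 rose by 3.44 ± 0.42, the receptor gene NOTCH3 by 2.62 ± 0.55 and FOXO4, a forkhead factor gene, by 2.45 ± 0.36. ETV5 fell by 3.67 ± 0.33 (adjusted p = 5.93e-13), from 1276 ± 257 to 122.2 ± 95.3 (SD), HES1 fell by 3.43 ± 0.35, ENDOD1 fell by 2.22 ± 0.23 and RAG1 fell by 2.15 ± 0.31. MYC fell by 1.28 ± 0.22 (adjusted p = 2.35e-05), with 2 of 3 other MYC probe sets of the same sign. CCND1, a D-type cyclin gene, rose by 1.44 ± 0.42 (lost without ethanol A or dexamethasone B, adjusted p = 0.0862 and 0.128) and CCND3 fell by 0.80 ± 0.17.

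The same lists shifted down in CEM C1-6. Of 29 MYC and MYC-activated genes 16 fell (19 adjusted over the list alone; median -0.71, adjusted p = 0.00251 with an estimated correlation), and of 23 ribosome biogenesis genes 16 fell (18 adjusted over the list alone; median -0.71, adjusted p = 0.00311 with an estimated correlation). Examples were PNO1 (-1.55 ± 0.23), a ribosome assembly factor gene, PPAT (-1.28 ± 0.26), of purine synthesis, and ODC1 (-1.14 ± 0.19). Of 16 heat shock protein genes 7 fell (10 adjusted over the list alone, adjusted p = 0.00685 with an estimated correlation), led by the mitochondrial chaperonin gene HSPE1 (-1.09 ± 0.19) and DNAJA1 (-0.78 ± 0.12). Among other groups shifted down, calls were lost. G1/S and replication genes had 10 of 39 lower and 1 higher (13 and 1 adjusted over the list alone, adjusted p = 0.078 with an estimated correlation). Proteasome genes had 8 of 30 lower (10 over the list alone, adjusted p = 0.124 with an estimated correlation), oxidative phosphorylation genes 6 of 46 (6 over the list alone, adjusted p = 0.48 with an estimated correlation), amino acid response genes 5 of 22 (8 over the list alone, adjusted p = 0.154 with an estimated correlation) and ER chaperone genes 3 of 12 (3 over the list alone, adjusted p = 0.106 with an estimated correlation). Members past the threshold were the proteasome gene PSMC1 (-0.63 ± 0.16), the replication factor gene RFC4 (-0.82 ± 0.16) and the complex I gene NDUFA9 (-0.90 ± 0.24). Without dexamethasone B, PPAT (adjusted p = 0.0576), PSMC1 (adjusted p = 0.24) and NDUFA9 (adjusted p = 0.202) were lost, and NDUFA9 also without ethanol A (adjusted p = 0.0704).

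Of 29 glucocorticoid-inducible genes 18 rose at 20 h in CEM C1-6 and 1 fell (19 and 2 adjusted over the list alone, adjusted p = 1.21e-08 with an estimated correlation). TSC22D3 was at 1.88 ± 0.26, TXNIP at 1.94 ± 0.25, IL7R at 2.06 ± 0.26 and NR3C1 at 1.05 ± 0.18, while TNFAIP3, an inhibitor of NF-kB signalling, fell by 0.79 ± 0.21. Of 10 pro-apoptotic BCL2 family genes 2 rose and 1 fell (3 and 1 adjusted over the list alone). BCL2L11 was at 0.91 ± 0.33 (adjusted p = 0.0566), which passed with replicate letters as a block (adjusted p = 0.0247). In simulations with no gene changed that fit called up to 359 genes with letters kept together and up to 1095 with arrays moved singly. Of the 4 tested anti-apoptotic genes BCL2L1, which encodes BCL-XL, fell by 1.13 ± 0.31 (adjusted p = 0.0104), a call lost without ethanol A or dexamethasone B (adjusted p = 0.0929 and 0.359) and with array weights (-0.54, adjusted p = 0.594). Myeloid markers showed 0 of 4 past the threshold in limma in each of the 3 clones at 20 h. The 25th percentile of the dexamethasone arrays was 53.8 ± 18.8 against 42.2 ± 7.31 (SD) in ethanol, and the array dexamethasone B had the highest of all, 73.6. Counts at 20 h were 319 without dexamethasone B, 437 without ethanol C, 1296 without dexamethasone C, 1058 with the replicate block and 116 with the 18 arrays of 20 h alone. Centring on array medians gave 127 that rose and 499 that fell, with the median of all genes moved to -0.19.

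In the resistant clone CEM C1-15 few genes passed the threshold, although the hormone-induced list shifted slightly upward. Limma found 0 genes at 2, 8 and 12 h (60, 52 and 65 at an unadjusted p under 0.05, against 294 by chance) and 2 at 20 h (338 unadjusted). FKBP5 rose by 1.49 ± 0.28 (adjusted p = 0.00855), from an intensity of 438.5 ± 90.1 to 1226 ± 207 (SD), and PTPRK, a receptor tyrosine phosphatase gene, fell by 1.36 ± 0.29 (adjusted p = 0.0414). BTG1 was at 0.87 ± 0.25 (adjusted p = 0.263), SOCS1 at 0.48 ± 0.35, NR3C1 at 0.16 ± 0.18 and MYC at 0.15 ± 0.22. At 8 h CD69 was at 1.21 ± 0.27 (adjusted p = 0.13). Of 29 glucocorticoid-inducible genes 0, 0, 0 and 1 rose at 2, 8, 12 and 20 h (1, 2, 1 and 5 adjusted over the list alone). The list's median was 0.17, 0.22, 0.27 and 0.26, and it was called up with an estimated correlation at each time (adjusted p = 0.00652, 4.64e-06, 1.05e-05 and 0.00272), though at 2 h fry did not call it (adjusted p = 0.478). NF-kB targets and regulators shifted up at 12 h (0 of 16 past in either adjustment, adjusted p = 0.0463 with an estimated correlation). They were not called by fry (adjusted p = 0.406) nor without ethanol B or dexamethasone A (adjusted p = 0.0997 and 0.188). A second probe set of TSC22D3, beside the brightest one used here, passed upward at each of the 4 times. MYC and MYC-activated genes (0 of 29 past in either adjustment, median -0.04) and ribosome biogenesis genes (0 of 23, median -0.05) were not called at 20 h.

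Other analyses of CEM C1-15 at 2, 8 and 12 h gave 35, 10 and 1 genes with array weights and 2, 3 and 1 with the 18 arrays of each time alone. At 20 h both of those gave 0, and without single arrays the count was 48 (ethanol C), 12 (ethanol B), 5 (dexamethasone A or dexamethasone C) and 0 (ethanol A). FKBP5 was lost without ethanol A (adjusted p = 0.0673) and without dexamethasone B (adjusted p = 0.0932), and PTPRK was lost without ethanol A, ethanol B, dexamethasone B or dexamethasone C (adjusted p = 0.507, 0.06, 0.183 and 0.208). PTPRK lay near the floor, and its value was -1.82 with the floor at the 10th percentile (adjusted p = 0.331) and -0.44 at the 40th (adjusted p = 0.612). It was also lost with median centring (adjusted p = 0.112) and the replicate block (adjusted p = 0.0651). The GAPDH 3' to 5' ratio of the 20 h arrays was 1.18 ± 0.241 in ethanol and 0.917 ± 0.0652 (SD) in dexamethasone, and with this ratio as a covariate 0 genes passed.

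The 2 sensitive clones shared calls at every time. BTG1 and SOCS1 rose in all 8 contrasts of the sensitive clones. DDIT4, FKBP5, NFIL3, NFKBIA, SLA, WFS1 and ZFP36L2 rose in 7 of 8, and ENDOD1, NKX2-5 and SATB1, a chromatin organiser of T cells, fell in 5. Genes called in the same direction in both clones numbered 2, 17, 44 and 201 at 2, 8, 12 and 20 h. At 20 h these were 92 that rose and 109 that fell, against 7.2 and 11 for independent lists of the same length, and 3 genes were called in opposite directions. The correlation of fold changes across genes, which are not independent replicates, was -0.053, 0.14, 0.29 and 0.46. In CEM C1-15, 154 of these 201 genes had the same sign and 1 was called. Their median log2 change in that direction was 0.11 there and, raised by selection, 0.81 and 0.82 in CEM C7-14 and CEM C1-6.

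Of the 60 genes called at 12 h in CEM C7-14, 56 were called in the same direction at 20 h, and in CEM C1-6 102 of 139 were. Of 317 genes called at any time in CEM C7-14, 253 were first called at 20 h, and of 741 in CEM C1-6, 568 were. This late excess was not seen in CEM C1-6 with the 18 arrays of each time alone, which gave 187 genes at 8 h and 116 at 20 h. In CEM C7-14 they gave 40 and 62. The ratio of the 20 h to the 12 h count was then 1.27 in CEM C7-14 and 1.04 in CEM C1-6. The excess was seen again when the replicate letters were added to that fit as a block, with 60 genes at 12 h and 199 at 20 h in CEM C7-14 and 180 and 459 in CEM C1-6. In simulations with no gene changed that fit called up to 418 genes at 20 h in CEM C7-14 and 0 in CEM C1-6 with letters kept together, and up to 5 and 242 with arrays moved singly. With at least a 2-fold change in both clones 2, 11, 24 and 55 genes were shared. The shared count at 20 h was 39 with the 18 arrays of 20 h alone, 104 with arrays centred on their medians and 131 without dexamethasone B of CEM C7-14. It was 11 at 8 h without ethanol B of CEM C7-14, and at 2 h it was 1 without ethanol B, ethanol C or dexamethasone C of that clone.

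**Figure D2:**
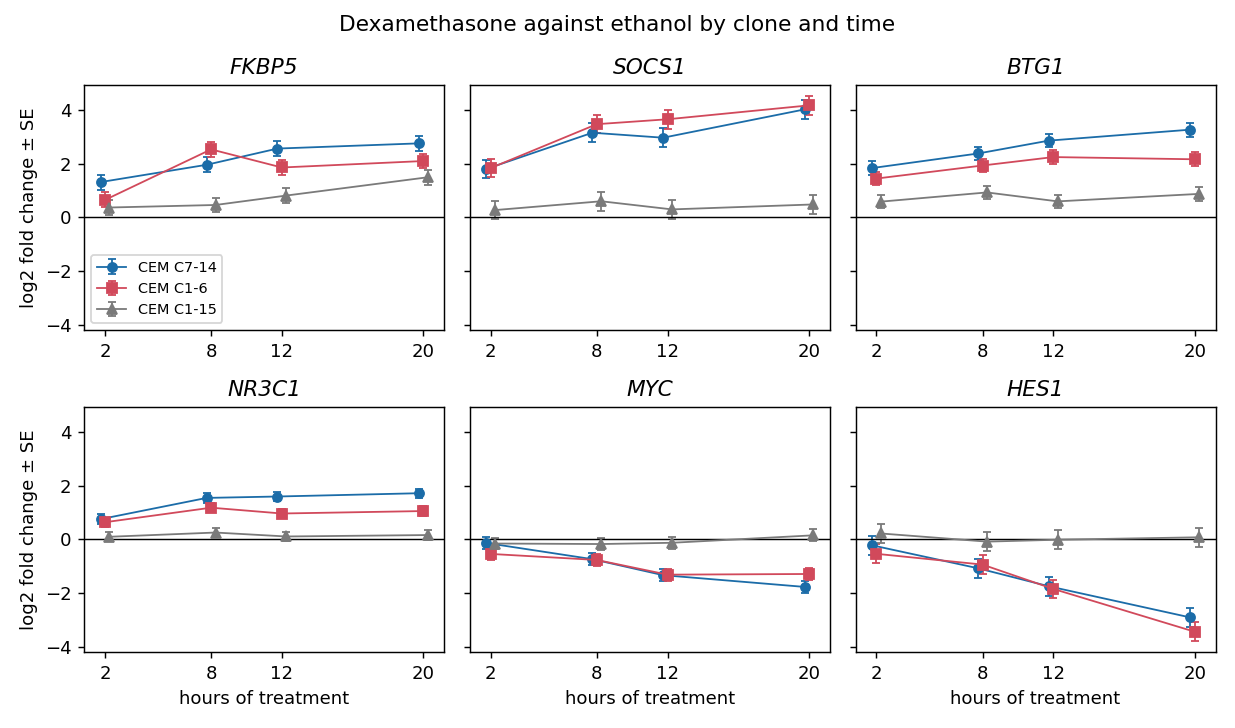
Log2 fold change of dexamethasone against ethanol (points, with bars for ± SE, n = 3 arrays per group) at 2, 8, 12 and 20 h in the 3 clones, 1 panel each for FKBP5, SOCS1, BTG1, NR3C1, MYC and HES1, with points of 1 time set slightly apart. SOCS1 reached 4.01 in CEM C7-14 and 4.16 in CEM C1-6 at 20 h and 0.48 in CEM C1-15, while MYC was at -1.76, -1.28 and 0.15.

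The test of sensitive against resistant asked which responses differed between the mean of the sensitive clones and CEM C1-15. At 20 h 83 genes had the more positive response in the sensitive clones and 76 the more negative one. SOCS1 differed by 3.60 ± 0.42 (adjusted p = 1.34e-08), CRYBG1 by 2.84 ± 0.33, PIK3IP1 by 2.40 ± 0.46, IL7R by 2.34 ± 0.32 and PRF1, which encodes perforin and passed in no single clone, by 2.27 ± 0.52. NR3C1 differed by 1.22 ± 0.22 (adjusted p = 0.000162), BTG1 by 1.84 ± 0.31, TXNIP by 1.32 ± 0.31 and NFKBIA by 1.15 ± 0.22. HES1 (-3.24 ± 0.43), RAG1 (-2.16 ± 0.38), MYC (-1.68 ± 0.27, adjusted p = 4.34e-05), NOP16, a nucleolar protein gene (-1.58 ± 0.38), and ODC1 (-1.18 ± 0.23) had lower responses. FKBP5 (0.93 ± 0.34, adjusted p = 0.144), TSC22D3 (0.81 ± 0.32, adjusted p = 0.186) and BCL2L11 (0.80 ± 0.40, adjusted p = 0.327) did not pass. At 2 h limma found 0 genes (56 at an unadjusted p under 0.05, 0 with the 18 arrays of 2 h alone and 7 with array weights). At 8 h all 10 that passed were higher, among them SOCS1 (2.70 ± 0.42), NFIL3 (1.54 ± 0.23) and NR3C1 (1.10 ± 0.22). At 12 h 17 were higher, with BTG1 at 1.95 ± 0.31 and RCAN1 at 2.08 ± 0.26, and 4 were lower, with HES1 at -1.78 ± 0.43 and MYC at -1.19 ± 0.27. Without dexamethasone A of CEM C1-6 or ethanol A of CEM C1-15 none of the 4 passed, and 14 and 11 were higher. HES1 at 12 h was lost without 9 of 18 single arrays (ethanol B, dexamethasone B or dexamethasone C of CEM C7-14, ethanol A or dexamethasone A of CEM C1-6, ethanol A, ethanol C, dexamethasone A or dexamethasone B of CEM C1-15, adjusted p = 0.0547 to 0.203). MYC at 12 h was lost without 5 (dexamethasone A of CEM C1-6, ethanol A, ethanol B, dexamethasone B or dexamethasone C of CEM C1-15, adjusted p = 0.0577 to 0.103). At 20 h NOP16 and PRF1 were lost without dexamethasone A of CEM C1-15 (adjusted p = 0.0793 and 0.0699) and TXNIP without its ethanol C (adjusted p = 0.0564).

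Glucocorticoid-inducible genes were called higher in the sensitive clones by camera at each time, though at 2 h 0 of 29 passed and fry did not call the list (adjusted p = 0.67). At 2, 8, 12 and 20 h 0, 6, 6 and 11 of 29 passed upward (2, 7, 10 and 14 adjusted over the list alone, with 1 lower at 8 h, adjusted p = 0.0227, 7.43e-08, 4.19e-08 and 1.92e-06 with an estimated correlation). At 20 h 10 of 29 MYC and MYC-activated genes (14 over the list alone, adjusted p = 0.00151 with an estimated correlation), 6 of 23 ribosome biogenesis genes (9 over the list alone, adjusted p = 0.00375 with an estimated correlation) and 2 of 16 heat shock genes (4 over the list alone, adjusted p = 0.013 with an estimated correlation) had lower responses. The difference for metallothioneins was lost (0 of 8 past, 3 over the list alone, adjusted p = 0.0988 with an estimated correlation). The 20 h count was 12 with the 18 arrays of 20 h alone, 251 without dexamethasone C of CEM C1-6, and 105 and 336 without ethanol B and ethanol C of CEM C1-15. The count was 6 at 8 h without dexamethasone C and 11 at 12 h without ethanol A of CEM C1-15, and centring on array medians gave splits of 15 and 1 at 12 h and 28 and 39 at 20 h.

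**Figure D3:**
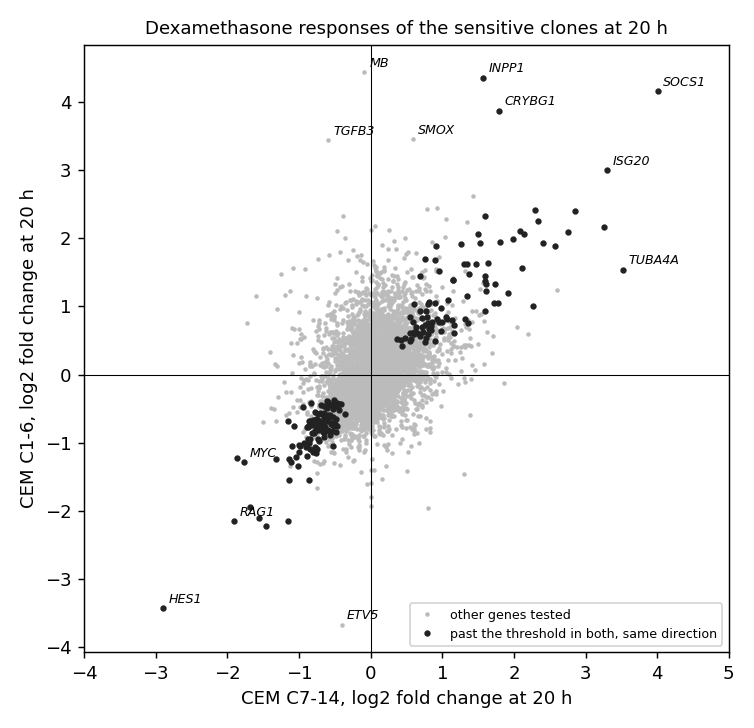
Log2 fold change of dexamethasone against ethanol at 20 h in CEM C7-14 (horizontal axis) and CEM C1-6 (vertical axis), 1 point per gene for 5883 genes. Dark points are the 201 genes called in the same direction in both clones, 92 in the upper right and 109 in the lower left, and MB, TGFB3 and SMOX lie high on the vertical axis alone (4.43, 3.44 and 3.45 in CEM C1-6).

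The sensitive clones differ in origin, and their responses were compared directly. At 2 h 1 gene differed, CRYBG1, whose response was lower in CEM C7-14 (-2.00 ± 0.38, adjusted p = 0.0131). With the floor at the 40th percentile it was -1.04 (adjusted p = 1). At 8 h all 11 that passed had the lower response in CEM C7-14, among them CRYBG1 (-3.13 ± 0.38), HBEGF, an EGF family growth factor gene (-2.60 ± 0.50), JAM3, an adhesion gene (-1.67 ± 0.36), and TSC22D3 (-1.56 ± 0.37). For TSC22D3 a second probe set, which had risen past the threshold in CEM C7-14, had the same sign in this difference and did not pass. JAM3 was lost without 8 of 12 single arrays (ethanol A, ethanol B, ethanol C, dexamethasone B or dexamethasone C of CEM C7-14, ethanol A, dexamethasone A or dexamethasone C of CEM C1-6, adjusted p = 0.0512 to 0.261). HBEGF was at -0.76 with the floor at the 40th percentile (adjusted p = 0.795). TSC22D3 was lost without any besides ethanol A of CEM C1-6 (adjusted p = 0.0658 to 0.359). At 12 h 3 passed: STAT4, a cytokine-activated transcription factor gene (2.52 ± 0.52), INPP1 (-2.87 ± 0.53) and CRYBG1 (-2.52 ± 0.38). At 20 h 13 were higher and 23 lower in CEM C7-14. TGFB3 (-4.04 ± 0.59, adjusted p = 1.51e-05), MB (-4.52 ± 0.72), SMOX (-2.86 ± 0.59), INPP1 (-2.78 ± 0.53) and the chemokine receptor gene CXCR3 (-2.71 ± 0.51) rose more in CEM C1-6. ETV5 (3.26 ± 0.46, adjusted p = 1.51e-05) and DGKG, a diacylglycerol kinase gene (2.76 ± 0.65), had the more negative response there, and TUBA4A (1.98 ± 0.42) had the larger response in CEM C7-14. DGKG was at 0.76 with the floor at the 40th percentile (adjusted p = 0.128) and was lost without dexamethasone A or dexamethasone C of CEM C7-14 or ethanol B or dexamethasone B of CEM C1-6 (adjusted p = 0.0517, 0.0936, 0.0798 and 0.0529). TUBA4A was lost without ethanol C of CEM C7-14 or dexamethasone B of CEM C1-6 (adjusted p = 0.0679 and 0.0529).

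Of 29 glucocorticoid-inducible genes 3 had the lower response in CEM C7-14 at 8 h (6 adjusted over the list alone, adjusted p = 0.00104 with an estimated correlation). At 20 h the camera calls of metallothioneins (0 of 8 past, 3 lower over the list alone), G1/S genes (0 of 39, 1 higher over the list alone), oxidative phosphorylation genes (0 of 46 in either adjustment) and proteasome genes (0 of 30 in either adjustment) were lost (adjusted p = 0.232, 0.503, 0.619 and 0.619 with an estimated correlation). With the 18 arrays of 1 time alone 0 genes passed in limma at 12 h and at 20 h. STAT4 at 12 h was lost without 1 of 6 single arrays (ethanol C, dexamethasone B or dexamethasone C of CEM C7-14, ethanol A, dexamethasone A or dexamethasone B of CEM C1-6; adjusted p = 0.0964, 0.0833, 0.0506, 0.108, 0.0564 and 0.136). Without single arrays of CEM C1-6 the 20 h count was 58 (dexamethasone A), 16 (dexamethasone B) and 100 (dexamethasone C), and the 12 h count was 5 (ethanol A) and 7 (dexamethasone C). Leaving out any 1 of the 12 arrays brought the 8 h count to between 2 and 7: in CEM C7-14 3 (ethanol A), 3 (ethanol B), 2 (ethanol C), 5 (dexamethasone A), 4 (dexamethasone B) and 4 (dexamethasone C), and in CEM C1-6 5, 7, 4, 3, 6 and 3 in that order. CRYBG1 at 2 h was lost without ethanol C or dexamethasone C of CEM C7-14 (adjusted p = 0.153 and 0.104) and without ethanol A, ethanol C or dexamethasone C of CEM C1-6 (adjusted p = 0.0502, 0.138 and 0.164), and without ethanol A of CEM C7-14 2 genes passed. Centring on array medians gave 1 higher and 10 lower at 12 h, and quantile normalization 1 and 7.

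The ethanol cultures showed how far the clones differed before any hormone. Against CEM C7-14, 1452 genes were higher and 1006 lower in CEM C1-15, and 1229 higher and 923 lower in CEM C1-6. CD1C and CD1A, which encode lipid antigen-presenting molecules of cortical thymocytes, were lower in both C1-derived clones. CD1C differed by -5.16 ± 0.17 and CD1A by -4.17 ± 0.23 in CEM C1-6, and by -3.60 ± 0.17 and -3.10 ± 0.23 in CEM C1-15. Mean CD1C intensity over the 12 ethanol arrays was 3698 ± 611 in CEM C7-14, 107.1 ± 35.2 in CEM C1-6 and 318.6 ± 120 in CEM C1-15 (SD). The mRNA-binding protein gene IGF2BP3 was higher in both (4.87 ± 0.14 and 4.74 ± 0.14), as was MLC1 (4.11 ± 0.11 and 4.22 ± 0.11). GLUL, which encodes glutamine synthetase, was lower in CEM C1-15 by -5.36 ± 0.14, and PTPRK was lower in both (-4.37 ± 0.14 in CEM C1-6 and -4.03 ± 0.14 in CEM C1-15). The co-stimulatory receptor gene CD28 (3.84 ± 0.11) and the transcription factor gene RUNX3 (3.66 ± 0.19) were higher in CEM C1-15 than in CEM C7-14. GDF10, a TGF-beta family gene, was higher in CEM C1-6 than in CEM C7-14 (5.68 ± 0.11) and than in CEM C1-15 (5.65 ± 0.11).

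The receptor gene NR3C1 had its lowest level of the 3 clones in the resistant one. Its mean intensity over 12 ethanol arrays was 487.3 ± 82.5 in CEM C1-15, 781.4 ± 103 in CEM C7-14 and 1289 ± 224 in CEM C1-6 (SD). The differences were -0.69 ± 0.09 for CEM C1-15 against CEM C7-14 (adjusted p = 1.81e-09), 0.71 ± 0.09 for CEM C1-6 against CEM C7-14 (adjusted p = 7.74e-10) and 1.40 ± 0.09 for CEM C1-6 against CEM C1-15 (adjusted p = 1.61e-20). SOCS1, which the hormone induced in the sensitive clones, was higher in ethanol cultures of CEM C1-15 than in those of CEM C7-14 (1.63 ± 0.17), as were TXNIP (1.18 ± 0.13) and the phosphatase gene DUSP1 (1.30 ± 0.17). The transporter genes ABCG1, whose product exports cholesterol (2.47 ± 0.14), and ABCB1, which encodes the multidrug transporter P-glycoprotein (2.00 ± 0.15), were higher in CEM C1-6 than in CEM C7-14 (2 of 5 efflux transporter genes in either adjustment, adjusted p = 0.0664 with an estimated correlation).

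Between the clones of C1 origin, 743 genes were higher and 886 lower in CEM C1-6 than in CEM C1-15. Cholesterol synthesis genes were higher in CEM C1-6, 15 of 17 over all genes and 16 adjusted over the list alone (adjusted p = 0.0118 with an estimated correlation), with HMGCS1 at 1.49 ± 0.19 and INSIG1 at 1.37 ± 0.12. Interferon response genes were higher, 11 of 21 in either adjustment (adjusted p = 0.0118 with an estimated correlation), with IFI35 at 2.18 ± 0.22, PSMB9, an immunoproteasome gene, at 2.16 ± 0.11 and IFI44 at 1.71 ± 0.16. Other list calls of this comparison were lost. Metallothioneins were higher in 7 of 8 in either adjustment (adjusted p = 0.0543 with an estimated correlation) and thymocyte genes higher in 5 and lower in 14 of 25 in either adjustment (adjusted p = 0.0543 with an estimated correlation). MYC and MYC-activated genes were lower in 15 of 29 (16 over the list alone, adjusted p = 0.144 with an estimated correlation), and ribosome biogenesis genes in 14 of 23 (15 over the list alone, adjusted p = 0.169 with an estimated correlation). Against CEM C7-14 no list call held: ribosomal protein genes were lower in 29 of 41 in CEM C1-15, in either adjustment, and in 23 of 41 in CEM C1-6 (26 over the list alone; adjusted p = 0.487 and 0.502 with an estimated correlation). ER chaperone genes (8 of 12) and histone genes (7 of 10) were higher in CEM C1-6 than in CEM C7-14, in either adjustment (adjusted p = 0.0616 for both with an estimated correlation). These 3 comparisons rest on 12 arrays per clone, and no left-out array moved a count by more than 1.5 times.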

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

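The tests of differences between clones were planned before the data were examined, while the counts over other splits of the arrays and the tests of explanations were chosen only after the results were seen.

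What drew attention was a response to dexamethasone that differed between clones by the test of the difference itself. Between the sensitive clones and CEM C1-15, 10 genes differed at 8 h, 21 at 12 h and 159 at 20 h. At 8 h the differences (log2) were 2.70 for SOCS1, 2.62 for CROCC, a centrosomal gene, 1.78 for FKBP5, 1.54 for NFIL3, 1.45 for CRYBG1, 1.18 for RCAN1, 1.10 for NR3C1 and 1.09 for NFKBIA. Of these, CRYBG1 was lost without 9 of 18 single arrays (adjusted p up to 0.163), RCAN1 without 7 (up to 0.204) and CROCC without 2 (up to 0.0777). At 12 h they were 3.0 for SOCS1, 2.08 for RCAN1, 2.03 for CRYBG1, 1.95 for BTG1 and for INPP1, 1.80 for TUBA4A, 1.75 for ISG20 and 1.62 for NFIL3, and -2.14 for ZNF202, -1.78 for HES1, -1.19 for MYC and -0.88 for NKX2-5. All 4 genes below 0 were lost without dexamethasone A of CEM C1-6 and without ethanol A of CEM C1-15. ZNF202 was lost without 12 of 18 single arrays (adjusted p up to 0.208), HES1 without 9 (up to 0.203), NKX2-5 without 8 (up to 0.139), INPP1 without 7 (up to 0.25) and MYC without 5 (up to 0.103). At 20 h they were 3.60 for SOCS1, 2.84 for CRYBG1, 2.78 for PPP2R3A, 2.65 for SMOX, 2.43 for TBKBP1, 2.40 for PIK3IP1, 2.34 for IL7R and 2.27 for PRF1. Those below 0 at 20 h were -3.24 for HES1, -2.16 for RAG1, -2.00 for ETV5, -1.85 for ARMC6, -1.84 for YLPM1, -1.71 for CCDC86, -1.68 for MYC and -1.58 for NOP16. Some of these differences rest on CEM C1-6 and not on CEM C7-14, which was at 0.23 for CRYBG1 at 8 h (3.36 in CEM C1-6), 0.45 for INPP1 at 12 h (3.31), 0.59 for SMOX at 20 h (3.45) and -0.41 for ETV5 at 20 h (-3.67). CROCC at 8 h passed in CEM C7-14 alone, and ZNF202 at 12 h and PPP2R3A, PRF1 and YLPM1 at 20 h passed in no single clone. Single arrays left out ended the calls of YLPM1 (5 of 18, adjusted p up to 0.118), TBKBP1, PRF1 and NOP16 (1 each, adjusted p = 0.0586, 0.0699 and 0.0793). Of 100 regroupings of the arrays, 100 gave as many genes at 2 h (0, highest other 0), 1 at 8 h (10, highest other 3), 2 at 12 h (21, highest other 42) and 16 at 20 h (159, highest other 1680), so the share was under 0.05 at 8 and 12 h and not at 2 and 20 h. Simulations with no gene changed reached at most 3 genes at 8 h (134 with the replicate block) but 75 at 12 h (a mean of 12.1 false calls in those with 200 genes changed). This argues against chance at 8 h, though so few regroupings and simulations cannot exclude it, and leaves it open at 12 h. The regrouping with 1680 points to a structure of the 20 h arrays, and with the dexamethasone and ethanol arrays of a letter kept together only 1 of 27 regroupings, the real one, gave as many at 20 h (highest other 83). Simulations of that kind with no gene changed reached 160, and in CEM C1-15 at 20 h the letters were not borne out as pairs (correlation -0.031 for letter A), so chance was not excluded at 20 h.

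Between CEM C7-14 and CEM C1-6 the count was 1 at 2 h, 11 at 8 h, 3 at 12 h and 36 at 20 h. The difference for CRYBG1 was -2.00 at 2 h. At 8 h it was -3.13 for CRYBG1, -2.60 for HBEGF, -1.67 for JAM3, -1.56 for TSC22D3 (whose second probe set rose past the threshold in CEM C7-14 and did not pass in this difference) and -1.49 for PPP1R13B. At 12 h it was 2.52 for STAT4, -2.87 for INPP1 and -2.52 for CRYBG1. At 20 h it was 3.26 for ETV5, 2.76 for CHRNA3 and for DGKG, 1.98 for TUBA4A and for ZHX2, -4.52 for MB, -4.04 for TGFB3, -2.86 for SMOX, -2.78 for INPP1 and -2.71 for CXCR3. Of 12 single arrays, those whose loss ended a call numbered 5 for CRYBG1 at 2 h, 11, 8 and 1 for TSC22D3, JAM3 and PPP1R13B at 8 h, 6 for STAT4 at 12 h, and 4, 2 and 1 for DGKG, TUBA4A and ZHX2 at 20 h. Of 100 regroupings, 1 gave as many at 2 h (highest other 0), 1 at 8 h (highest other 1), 3 at 12 h (highest other 10) and 28 at 20 h (highest other 1378), and the regrouping with 1378 points to a structure of the 20 h arrays. Simulations with no gene changed reached 1 at 2 h, 2 at 8 h and 194 at 12 h (a mean of 20.6 false calls in another set of 20). This leaves chance open at 2, 12 and 20 h and argues against it at 8 h without excluding it. The 8 h count fell to between 2 and 7 without any 1 of the 12 arrays, and to 2 with median centring. With the 18 arrays of 1 time alone 0 genes passed in limma at 12 h and at 20 h.

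For the ethanol cultures 1 of 100 regroupings, the real one, gave as many genes in each comparison. The counts were 2458 for CEM C1-15 against CEM C7-14 (highest other 2311), 2152 for CEM C1-6 against CEM C7-14 (highest other 1159) and 1629 for CEM C1-6 against CEM C1-15 (highest other 633). For genes shared by CEM C7-14 and CEM C1-6, 1 of 100 pairs of splits gave as many at each time (2, 17, 44 and 201 genes, highest others 0, 0, 2 and 82).

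For dexamethasone against ethanol in 1 clone at 1 time, 6 arrays allow 10 splits, and the share is never under 0.1, so the splits are too few. Any real difference stayed in the values of these splits as well. At 2, 8, 12 and 20 h the counts were 4, 21, 60 and 310 in CEM C7-14 (highest others 1, 1, 1 and 249), 11, 93, 139 and 689 in CEM C1-6 (1, 1, 65 and 1081) and 0, 0, 0 and 2 in CEM C1-15 (0, 12, 1 and 279). The split with 279 points to a structure of the 20 h arrays of CEM C1-15. Letters paired the arrays in CEM C7-14 and CEM C1-6 at 20 h. There the splits with 249 and 1081 left both arrays of 1 letter on the same side, and the other splits that part all letters gave at most 1 and 2 genes.

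The first pattern was the larger count at 20 h than at 12 h in both sensitive clones. Without the 6 arrays of letter A at 20 h the 20 h counts were 235 and 666 in CEM C7-14 and CEM C1-6, and with low-end signal as a covariate the ratio of 20 h to 12 h was 5.45 and 3.21, which argues against either as the whole cause. Chance deviations that are independent in the clones would not raise the covariance of their fold changes on average, but they can in a single draw. Its lowest value with 1 array left out was 0.08 at 20 h against at most 0.0547 at 12 h. Leaving out arrays shows the weight of single arrays and cannot decide on chance. At 20 h the covariance was 0.106 over all arrays. Over other pairs of splits its size reached 0.0427 where all letters were parted and 0.133 where some were not. Chance and a structure by letter that the clones share therefore both stay open. A spread shared by all times, while arrays of 20 h vary more, cannot be told apart from a wider response, since with the spread of each time alone the ratios were 1.27 and 1.04. With the replicate block added to that fit the counts at 12 and 20 h were 60 and 199 in CEM C7-14 and 180 and 459 in CEM C1-6, which goes against this explanation. It stays open all the same. Every letter paired the cultures at 20 h in these clones, while at 12 h letter A did not (-0.036 in CEM C7-14 and -0.11 in CEM C1-6). Simulations of this fit with no gene changed also reached 418 in CEM C7-14 and 242 in CEM C1-6. A response that widens with time is a hypothesis found and tested on the same data.

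The second pattern was the fall of MYC and ribosome biogenesis lists at 20 h in the sensitive clones. Under the 2 other scalings the weakest medians of the MYC list were -0.54 in CEM C7-14 and -0.66 in CEM C1-6, and those of the ribosome biogenesis list were -0.66 (-0.658) and -0.84 (-0.841). With low-end signal or the 3' to 5' ratio as a covariate they were -0.60 (-0.602) and -0.62 (-0.615) for the MYC list, and -0.54 (-0.535) and -0.61 (-0.614) for the ribosome biogenesis list. These values argue against scaling, low-end signal and RNA integrity as the whole cause. A response to the hormone that the resistant clone lacks may account for it. Both lists differed between sensitive and resistant clones (larger adjusted p = 0.00375 with an estimated correlation). That comparison uses the same arrays of the sensitive clones, so it is not a separate test of this cause.

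The third pattern was the low number of calls in CEM C1-15. A larger spread of its arrays would not alter the response size. Yet the glucocorticoid-inducible list differed by a median of 0.808 between sensitive and resistant clones at 20 h. Cultures without hormone would leave this list at 0, yet it was called up at 4 of 4 times with an estimated correlation, although fry missed it at 2 h (adjusted p = 0.478). At 2, 8 and 12 h too wide a shared spread may hide calls. Lower NR3C1 in ethanol cultures (-0.69 against CEM C7-14) may be related but, with 1 resistant clone, cannot be told apart from other clone differences.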

How the results depend on the processing

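Array weights, fits on the arrays of 1 time (with and without the replicate block), the low-end and 3' to 5' covariates and both treatments of the 6 arrays of letter A at 20 h were chosen after the data were seen, and the other alternatives before. Where no construction is named for a changed value, the cause was not tested. Of 444 named gene calls 0 changed sign (not checked with all probe sets). Calls lost numbered 187 with the compared groups alone, 109 of 283 with the arrays of 1 time, 54 of 283 with the block added, 53 with median centring, 51 with array weights, 25 with quantile normalization, 23 of 319 without the 6 arrays, 21 with no filter, 19 with the 3' to 5' covariate, 14 with the floor at the 40th percentile or the low-end covariate, 13 without the variance trend, 9 with the floor at the 10th percentile, 5 with the replicate block, 0 of 377 with a stricter filter, and 464 of 6336 over all single arrays left out. Of 131 list calls 93 were lost with an estimated correlation, 57 with fry, 32 with quantile normalization and 32 with array weights, and over the 12 dexamethasone contrasts 28 of 74 calls held with an estimated correlation. Cytosolic ribosomal proteins in CEM C7-14 at 20 h turned from -0.10 to 0.05 (0.0502) with quantile normalization.

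Calls of single genes with a printed value that were lost with median centring included IARS1, NARS1, LEF1, TOB1, TAL1, CDKN1B and MSMO1 in CEM C7-14 at 20 h, CRYBG1 and RCAN1 at 8 h, HES1, MYC and NKX2-5 at 12 h and TXNIP at 20 h for sensitive against resistant, and JAM3, PPP1R13B and TSC22D3 at 8 h and DGKG at 20 h for CEM C7-14 against CEM C1-6. With array weights they included CD1E, MSMO1 and TAL1 in CEM C7-14 at 20 h, RFC4, PSMC1, NDUFA9, CCND1 and BCL2L1 in CEM C1-6 at 20 h, FKBP5 and PTPRK in CEM C1-15 at 20 h, NOP16, PRF1, PPP2R3A, YLPM1 and TXNIP at 20 h for sensitive against resistant, and STAT4 at 12 h and CHRNA3, DGKG, INPP1, SMOX, TUBA4A and ZHX2 at 20 h for CEM C7-14 against CEM C1-6. Without the 6 arrays of letter A, SMOX for sensitive against resistant went from 2.65 to 1.65 (adjusted p = 0.138) and PRF1 from 2.27 to 1.26 (adjusted p = 0.416). With the floor at the 40th percentile ZNF202 was at -0.87 (adjusted p = 0.499) and YLPM1 at -0.98 (adjusted p = 0.182). Folds that shrank with that floor while the call held included SOCS1 in CEM C7-14 at 8 h (1.89), RRP12 there at 20 h (-1.13), CRYBG1 in CEM C1-6 at 2 h (1.13), and ABCG1 (1.29) and ABCB1 (1.03) in ethanol cultures of CEM C1-6 against CEM C7-14.

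With 1 array left out, counts at 2, 8, 12 and 20 h ranged over 1 to 6, 12 to 17, 39 to 52 and 195 to 323 in CEM C7-14. In CEM C1-6 they ranged over 8 to 11, 53 to 74, 76 to 180 and 319 to 1296, and in CEM C1-15 over 0 to 0 at 2, 8 and 12 h and 0 to 48 at 20 h. For sensitive against resistant the ranges were 0 to 0, 6 to 11, 11 to 24 and 105 to 336, for CEM C7-14 against CEM C1-6 0 to 2, 2 to 7, 2 to 7 and 16 to 100, and for shared genes 1 to 2, 11 to 16, 30 to 41 and 131 to 200. In the ethanol comparisons they were 2307 to 2526, 2048 to 2162 and 1501 to 1663.

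The replicate block, in which letters pair the cultures, gave 432 genes in CEM C7-14 at 20 h and 1058 in CEM C1-6 at 20 h, the 2 combinations where the check bore out the pairing. In simulations with letters kept together and no gene changed the same fit reached 1253 and 359, so the gain is not evidence of more responding genes. There it changed 1 named call (BCL2L11 in CEM C1-6, adjusted p = 0.0247) and no other call of a named gene or list. Some letters were correlated outside these 2 as well. Letter C reached 0.35, 0.33 and 0.34 at 12 h in CEM C7-14, CEM C1-6 and CEM C1-15, and 0.39 in CEM C1-15 at 20 h. Between clones the median for letter C at 12 h was 0.22. Elsewhere the check still did not bear out every letter, and each letter matched its own best in no other combination. There the block gave 7 and 95 in CEM C7-14 at 2 and 12 h, 169 and 230 in CEM C1-6 at 8 and 12 h, 1 and 3 in CEM C1-15 at 2 and 8 h, 34 and 310 for sensitive against resistant at 12 and 20 h, 13 for CEM C7-14 against CEM C1-6 at 12 h and 5 shared genes at 2 h.

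With the arrays of the compared groups alone, which leaves 4 residual degrees of freedom in a dexamethasone contrast, counts at 2, 8, 12 and 20 h were 0, 4, 18 and 51 in CEM C7-14 and 2, 42, 39 and 25 in CEM C1-6. CEM C1-15 had 2, 1 and 0 at 2, 12 and 20 h. Shared genes numbered 0, 4, 13 and 9, CEM C7-14 against CEM C1-6 gave 0, 7, 0 and 0, and sensitive against resistant gave 12 at 20 h.

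Fits with the 18 arrays of 1 time leave out the spread of other times. Their 8 and 20 h counts were 40 and 62 in CEM C7-14 and 187 and 116 in CEM C1-6. CEM C1-15 had 2, 3, 1 and 0 at 2, 8, 12 and 20 h, shared genes numbered 5, 26 and 39 at 2, 8 and 20 h, CEM C7-14 against CEM C1-6 gave 0 at 12 and 20 h, and sensitive against resistant gave 12 at 20 h. With the replicate block added the counts were 7 and 199 in CEM C7-14 at 2 and 20 h, 459 in CEM C1-6 at 20 h, 2, 2, 1 and 1 in CEM C1-15, 4 and 133 shared at 2 and 20 h, 0, 7, 5 and 0 for CEM C7-14 against CEM C1-6 and 53 for sensitive against resistant at 20 h.

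With array quality weights the counts were 15, 53 and 107 in CEM C7-14 at 2, 8 and 12 h, 25, 177 and 330 in CEM C1-6 at 2, 8 and 20 h, and 35, 10, 1 and 0 in CEM C1-15 at 2, 8, 12 and 20 h. Shared genes numbered 9 and 32 at 2 and 8 h. Sensitive against resistant gave 7, 19, 38 and 58, and CEM C7-14 against CEM C1-6 gave 3, 27, 8 and 9.

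Centring on array medians gave 2, 33 and 165 in CEM C7-14 at 2, 12 and 20 h, 6 and 53 in CEM C1-6 at 2 and 8 h, 1 in CEM C1-15 at 20 h, 28 and 104 shared at 12 and 20 h, 67 for sensitive against resistant at 20 h, and 2, 11 and 19 for CEM C7-14 against CEM C1-6 at 8, 12 and 20 h. It moved the median of all genes by more than 0.1 in several contrasts, to -0.11 and 0.11 in CEM C7-14 at 2 and 8 h, to 0.12 and -0.16 for sensitive against resistant at 12 and 20 h, and to -0.14, 0.22, -0.24 and 0.15 for CEM C7-14 against CEM C1-6. Quantile normalization gave 1 gene in CEM C7-14 at 2 h, 1 shared at 2 h, and 7 and 8 for CEM C7-14 against CEM C1-6 at 8 and 12 h.

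Low-end signal as a covariate gave 9 in CEM C7-14 at 2 h, 1 and 1 in CEM C1-15 at 8 and 12 h, 4 shared at 2 h and 8 for CEM C7-14 against CEM C1-6 at 12 h, and the 3' to 5' covariate gave 0 in CEM C1-15 at 20 h. Without the 6 arrays of letter A at 20 h, sensitive against resistant gave 100 at 20 h, and CEM C7-14 and CEM C1-6 gave 235 and 666. With the floor at the 10th percentile CEM C1-15 had 1 at 20 h, and with the floor at the 40th it had 1 while CEM C7-14 against CEM C1-6 gave 0, 16 and 56 at 2, 12 and 20 h. With no filter, and so more genes tested, CEM C1-15 had 2, 1 and 36 at 2, 12 and 20 h and CEM C7-14 against CEM C1-6 gave 7, 5 and 58 at 8, 12 and 20 h. A stricter filter gave 1 in CEM C1-15 at 20 h, where PTPRK was no longer tested. All probe sets gave 1, 1, 1 and 4 in CEM C1-15 and 5 for CEM C7-14 against CEM C1-6 at 12 h, and dropping the variance trend gave 7 for CEM C7-14 against CEM C1-6 at 8 h. Shared genes with at least a 2-fold change in both clones numbered 11, 24 and 55 at 8, 12 and 20 h. Detection calls were not used here, so genes near the floor of 34.1 have fold changes that the background limits.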

Other observations

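The gene groups described first were fixed before the data were examined, while their members were chosen after their values were seen, and both tests that follow were written down before their results were seen.

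Single genes linked to lymphocyte function passed the threshold after 20 h of dexamethasone, while the lists of T cell receptor signalling and of adhesion held no call. In CEM C1-6, 5 of 26 genes of T cell receptor signalling rose and 2 fell, in either adjustment, and in CEM C7-14 1 rose (4 adjusted over the list alone), and camera called the list in neither clone. CD53, a tetraspanin of leukocytes, rose in CEM C7-14 (1.64 ± 0.26) and in CEM C1-6 (1.64 ± 0.26). The kinase gene LCK fell by 0.80 ± 0.12 in CEM C1-6 and was at -0.09 ± 0.12 in CEM C7-14. Of 7 B cell markers 1 rose in CEM C7-14 and 3 in CEM C1-6, in either adjustment. Of 29 adhesion and cytoskeleton genes 6 rose and 1 fell in CEM C1-6, in either adjustment, and the list's call was lost (adjusted p = 0.0936 with an estimated correlation). CD99 rose (0.88 ± 0.15). Among genes of the BCL2 family and the caspase pathway, CYCS, which encodes cytochrome c, fell in CEM C1-6 by 0.97 ± 0.18, and BIK rose there by 1.01 ± 0.21. The genes given here are members whose calls held without each single array, with median centring and with the 18 arrays of 20 h alone. With the arrays of the compared groups alone their calls in CEM C1-6 were lost (adjusted p = 0.0533 to 0.387).

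Some B cell and redox genes differed between the ethanol cultures, although no call of these lists held. IGLL1, a surrogate light chain gene of early B cells, was lower in CEM C1-15 than in CEM C7-14 (-2.59 ± 0.14), and CD79A was lower as well (-1.64 ± 0.12). These were 2 of 7 B cell markers, in either adjustment (adjusted p = 0.392 with an estimated correlation), and both were higher in CEM C1-6 than in CEM C1-15 (2.35 ± 0.14 and 1.17 ± 0.12, with 3 of 7 higher in either adjustment and adjusted p = 0.112 with an estimated correlation). Of 19 redox and glutathione genes 8 were lower and 3 higher in CEM C1-6 than in CEM C1-15 (10 and 4 adjusted over the list alone, adjusted p = 0.382 with an estimated correlation). The lower ones included glutathione reductase (GSR, -1.31 ± 0.15), the quinone reductase gene NQO1 (-1.04 ± 0.13) and thioredoxin reductase (TXNRD1, -0.75 ± 0.07).

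One hypothesis was that genes whose response at 20 h differs between CEM C7-14 and CEM C1-6 also tend to differ between these clones without hormone. To keep the group means separate, ethanol cultures of 2, 8 and 12 h were used for the second part. Both parts still used the same spread per gene, estimated from all 72 arrays, so a gene of small spread passes both more easily. Over 795 genes past the threshold at 20 h in either clone or in the difference, 26 of 36 with a differing response (72.2%) also differed between the ethanol cultures, against 359 of 759 others (47.3%). The odds ratio was 2.89 (Fisher's exact test, two-sided, p = 0.00359). In 18 of the 26 the more positive response was in the clone with the lower ethanol level. The result goes in the direction of the hypothesis, but the shared spread could raise the odds ratio by itself, and genes are not independent replicates. With the 18 arrays of 20 h alone 0 of these differences in response passed in limma.

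Ethanol cultures of 20 h were set against those of 2 h to see whether time in culture alone moved genes. In this comparison 34 genes were higher and 40 lower in CEM C7-14, 186 and 302 in CEM C1-6, and 615 and 876 in CEM C1-15. Without the arrays of letter A at 20 h the totals were 201, 249 and 1045. In all 3 clones 13 genes moved the same way, 4 higher and 9 lower at 20 h. TXNIP, which the hormone raised in the sensitive clones, was lower by -1.53, -1.09 and -1.28 in CEM C7-14, CEM C1-6 and CEM C1-15 (SE 0.25 each), and the coat protein gene SEC13 by -1.26, -1.38 and -1.29 (SE 0.3 each). Cholesterol synthesis genes had a median of -0.56 in CEM C1-6 (17 tested, adjusted p = 0.0193 with an estimated correlation). Ribosomal protein genes had a median of 0.40 in CEM C1-6 and 0.82 in CEM C1-15 (41 tested), and neither call held (adjusted p = 0.4 and 0.0669 with an estimated correlation). Time in culture, a separate handling of the 20 h arrays and RNA integrity cannot be told apart here, because the labels give no array batch and each time was a set of cultures of its own.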
